A study of Mus musculus with 6 samples.

How the data were processed

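Bulk RNA sequencing was available for 6 libraries of developing mouse cerebellum at postnatal day 18: 3 from wild-type (WT) mice and 3 from mice lacking the remote enhancer of Atoh7 (KO). The protocol in the labels describes the replicates of each genotype as independent. The tissue entry of each sample reads retina while the series design and the protocol read cerebellum, so the levels of marker genes of both tissues are given in the results, and no group was changed because of them. Groups and replicate numbers were taken from the sample titles. The deposited file of KO replicate 3 has another prefix in its name than those of the other KO replicates; the title was followed.

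The deposited files hold raw counts of reads per gene, one file per library, and they are not normalized. Reads were trimmed with Trimmomatic and aligned and counted with STAR on the mm10 genome, per the submitters' processing notes; the tool versions, the gene annotation, the library kit's strand setting and the batches of library preparation are not given in the sources used here. Each file has 24411 gene symbols, a column of counts without regard to strand and a column for each strand, preceded by 4 summary lines (unmapped reads, reads with several places in the genome, reads outside genes and reads in more than 1 gene). Reads outside genes are those that overlap no exon on the counted strand, so reads in introns or on the strand opposite a gene are among them. The summary lines were left out of library sizes and tests. Their shares of all reads were, as the mean of the 3 WT and of the 3 KO libraries, 10.1% and 6.87% for unmapped reads, 7.39% and 9.28% for reads with several places, and 34.3% and 17.3% for reads outside genes on the counted strand. Reads in more than 1 gene were at most 0.458% of a library. The strand columns differed by a ratio of 55.4 over all libraries, above the ratio of 5 set as the rule, so the column of the heavier strand was used. A read that overlaps an unspliced intron only is not counted for a gene in such a table, and reads shared by near-identical copies are dropped as having several places, so genes with such copies are uncertain.

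Genes with low counts were removed with edgeR's filterByExpr, which left 15519 genes and removed 8892. Library sizes were scaled by the trimmed mean of M values (TMM), and KO was compared with WT by edgeR's quasi-likelihood test (glmQLFit and glmQLFTest with robust estimation, edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are KO minus WT. Their standard errors (SE) were obtained as the absolute log2 fold change divided by the square root of the F statistic and are approximate. CPM (counts scaled to 1e+06 reads per library) were computed with the TMM-scaled library sizes, and log2 CPM with a prior count of 2. Gene groups were compared with all other genes by camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 31 lists. The test was repeated with the correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, in 1 direction. Measures of the libraries were compared by a two-sided exact permutation test, which with 3 against 3 libraries cannot give a p under 0.1. Shares of genes were compared by a two-sided Fisher's exact test. Intervals are at 95% and cover counting error only, since PCR copies are not independent molecules. The value of 3 counts in a library corresponds to 0.0871 to 0.184 CPM without TMM scaling.

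The gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined, except where the text says otherwise. The 31 lists cover the neighbours of Atoh7, proneural transcription factors, the cell types of the cerebellum and its coverings, brainstem, 3 groups of retinal cells, synapse, ion channel and axon guidance genes, stress, hormone, clock, sterol, interferon, blood, mitochondrial and ribosomal genes, and genes that mark sex or differ between mouse strains. The rule named Atoh7; its listed neighbours past the threshold when adjusted over the list alone; up to 12 genes higher and 12 lower with the largest fold changes among those past the threshold, with a mean of at least 1 CPM and no overlap between the 3 WT and 3 KO libraries; up to 4 members with the smallest p of each cell type list and each list past the camera test; and 3 retinal and 3 cerebellar genes for the tissue. Unnamed gene models were passed over unless among the first 5. Some genes named by the rule are not reported here, nor counted among the named genes under the alternatives. Other genes in the text are members of the lists, copies of named genes (Tuba1a, Tuba1b, Rpph1), genes of chromosome windows, or Rn45s, and they were chosen after their values were seen.

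Gene positions and biotypes came from the GENCODE annotation of GRCm38, the assembly that mm10 denotes, matched by symbol for 23379 of the 24411 genes. GC content was known for 96.3% of tested genes. Alternatives were other scalings (RLE, upper quartile), other count filters, DESeq2 1.42.0, limma-voom with and without sample quality weights, estimation without the robust step, the replicate number as a block, counts without regard to strand, removal of genes above 1% of a library, a covariate for sex, a minimum change of 1.2 fold, a threshold of 0.1, and each library left out in turn. A trend on GC content and gene length and a covariate for read assignment were added after seeing the data. So were list counts without libraries that stood apart and 2 lists of nuclear RNAs, whose camera and fry p were adjusted over all 33 lists. The covariate was the log2 ratio of reads outside genes to gene reads other than Rn45s. That ratio was 2.95 in WT replicate 3, 0.617 and 0.612 in WT replicates 1 and 2, and 0.259 to 0.270 in KO libraries. Within groups the ratio varied almost only through WT replicate 3, so a fit with the covariate cannot separate read assignment from that library.

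The procedure was tested on simulated counts for KO against WT drawn for 15519 genes with the observed means, spreads and library sizes, in 5 runs with 200 genes changed in each. It recovered 77.9% of genes changed by 1.5 fold, 92.5% by 2 fold and 99.1% by 3 fold, and 9.25% of its calls were false. The vascular list, shifted down in every run, was found in 5 of 5 runs, and 0 other lists were called. The simulation gave genes independent errors and so did not test the list comparison when genes vary together. Replicates were checked for duplicates: the chi-square statistic per degree of freedom was at least 6.70 for every pair of libraries, so the counts of no pair agreed within sampling noise. Figures were drawn with matplotlib from the values reported.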

Results

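RNA was sequenced from the cerebellum of mice at postnatal day 18, in 3 independent WT replicates and 3 independent replicates from mice without the remote enhancer of Atoh7, a regulatory element of a proneural transcription factor gene best known from the birth of retinal ganglion cells. The series asks about the role of this element in the retina, and the cerebellum is a brain region in which the same deletion was profiled. Libraries held 46160747 to 51947647 reads. Reads assigned to genes numbered 28170761, 26812996 and 16340132 in WT replicates 1 to 3 and 32556977, 32992424 and 34438262 in KO replicates 1 to 3.

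Some libraries stood apart. In WT replicate 3, 63.2% of gene reads came from Rn45s, the ribosomal RNA precursor, against 1.28% to 3.04% in the other libraries, which left 6015125 reads on other genes, and 18.2% of its reads were unmapped. Reads outside genes, introns included, made up 34.3% ± 3.59 of WT and 17.3% ± 0.291 of KO libraries (SD, n = 3 each). The groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Xist, the RNA of the inactive X chromosome, had 31134 reads in WT replicate 1, which had 0 reads on Y-linked genes, and at most 10 reads in any other library, so WT replicate 1 is the only library with a female pattern.

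**Figure D1:**
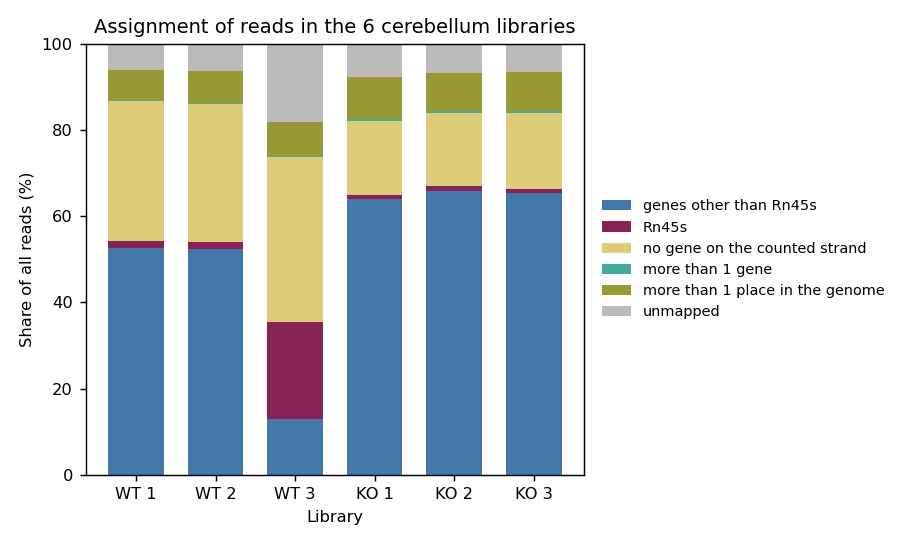
Each bar splits the reads of a library (x axis) into shares of all reads in percent (y axis): genes, Rn45s, reads outside genes on the counted strand, reads in more than 1 gene, reads with several places in the genome, and unmapped reads. Reads outside genes, introns included, are 32.0% to 38.5% in the 3 WT and 17.1% to 17.6% in the 3 KO libraries. Rn45s is prominent in WT replicate 3 only.

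Atoh7 was expressed at a low level in cerebellum of both genotypes. The gene (chromosome 10, 63099651 to 63101279, GRCm38) had 72, 56 and 7 reads in WT replicates 1 to 3 and 45, 54 and 92 reads in KO replicates 1 to 3. Its level was 1.64 ± 0.510 CPM in WT and 1.58 ± 0.559 CPM in KO (SD, n = 3 each), a log2 fold change of −0.18 (SE 0.28; adjusted p = 0.706 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The difference was smaller than the spread between replicates, and the labels describe the deleted element as remote from the gene, so the level does not check the genotype labels. Its sign turned without WT replicate 1 (0.014) and without KO replicate 1 (0.0082).

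Among genes around Atoh7, 1 of 16 measured list members rose in KO, 4 fell and 11 did not pass the test. Rufy2, an endosomal adaptor gene, fell by 0.70 on the log2 scale (SE 0.08), from 59.2 ± 4.12 to 36.2 ± 2.23 CPM (SD, n = 3 each). Sirt1, a NAD-dependent deacetylase (log2 −0.55, SE 0.09), Dna2, a helicase and nuclease of DNA replication (−1.02, SE 0.18), and Herc4, a ubiquitin ligase (−0.37, SE 0.08), fell as well. Slc25a16, a mitochondrial carrier, rose by 0.37 (SE 0.09). These genes lie at 62.9 to 63.4 Mb, on both sides of Atoh7, with adjusted p from 3.01e-04 (Rufy2) to 0.0204 (Slc25a16) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. When adjusted over the list alone, 9 members passed, the additional ones being Hnrnph3 (−1.05), Ccar1 (−0.46), Ddx50 (−0.22) and Ctnna3 (−0.42). Without WT replicate 3, Hnrnph3 was at −0.68 (adjusted p = 0.00366) and Ccar1 at −0.28 (0.00696). Without WT replicate 1, Ccar1 was at −0.59 (0.00830) and Ctnna3 at −0.54 (0.0341). These 4 values are past the threshold over all genes. The read assignment covariate, the log2 ratio of reads outside genes to gene reads other than Rn45s, was added after seeing the data. Within groups it varied almost only through WT replicate 3, so calls kept or lost with it cannot separate read assignment from that library. With the covariate, Hnrnph3 was at −0.06, Ddx50 at −0.07, Ctnna3 at −0.26 and Ccar1 at 0.01, a turned sign. Herc4 (−0.18, adjusted p = 0.314) and Slc25a16 (0.41, adjusted p = 0.0891) lost their calls, and Rufy2 (−0.58), Sirt1 (−0.50) and Dna2 (−1.22) kept theirs. The share of changed members, 31.3%, compares with 16.6% of all other tested genes (two-sided Fisher's exact test p = 0.167). Camera gave the list an adjusted p of 0.268. The call of Herc4 was lost without KO replicate 1, 2 or 3 and that of Slc25a16 without WT replicate 1 or 2 or KO replicate 2. Without KO replicate 2 the count was 3 in place of 5, as with the covariate.

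**Figure D2:**
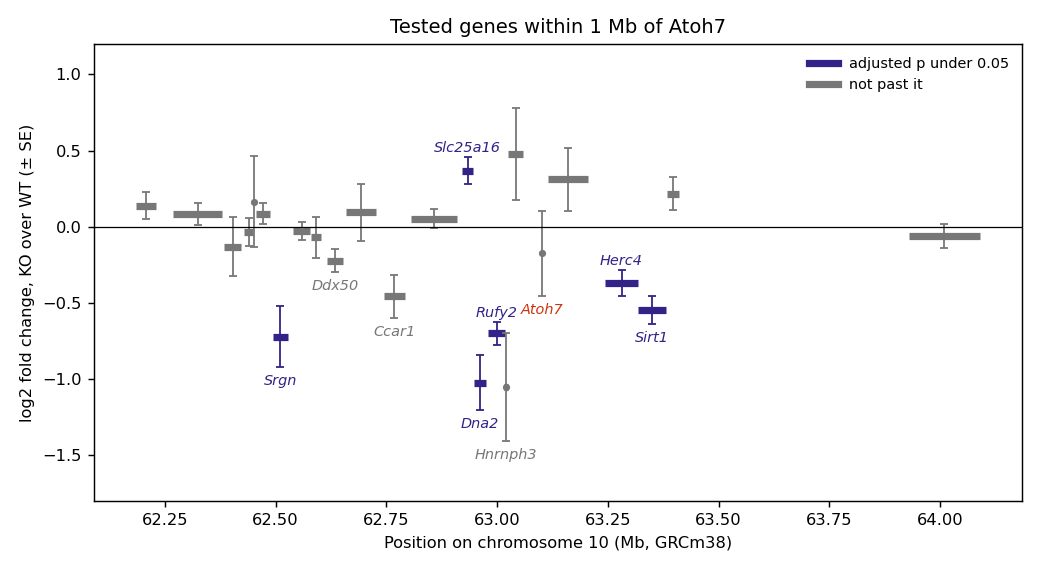
Tested genes within 1 Mb of Atoh7 are drawn at their position on chromosome 10 in Mb (x axis) against their log2 fold change, KO over WT (y axis); horizontal bars span the gene, vertical bars are ± SE, and dark bars mark genes past an adjusted p of 0.05. Of 23 such genes other than Atoh7, 6 passed, 5 of them lower, including Srgn (−0.72), which is outside the list and was singled out after its value was seen, and Atoh7 itself lies at −0.18.

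Across the transcriptome, 2585 of 15519 tested genes (16.7%) differed between KO and WT in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 998 rose and 1587 fell. Most changes were modest, with a median absolute log2 fold change of 0.40 among changed genes. Of the genes that rose, 57 reached 1.5 fold and 19 reached 2 fold. Of those that fell, 680 reached 1.5 fold and 272 reached 2 fold. The groups did not overlap in 6112 genes (39.4%), where chance gives 10%. The numbers depended on single libraries: 1331 genes passed without WT replicate 2 and 1289, 1130 and 1041 without KO replicates 1, 2 and 3. Genes that rose numbered 1623 without WT replicate 3 and 408 without WT replicate 2, and 356, 295 and 245 without KO replicates 1 to 3; genes that fell numbered 923 without WT replicate 2 and 933, 835 and 796 without KO replicates 1 to 3.

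The gene with the smallest p was Tuba1c, an alpha-tubulin gene (chromosome 15, 99029891 to 99038110), which rose from 2.51 ± 0.244 to 31.0 ± 3.63 CPM (SD, n = 3 each), 12.8 fold (log2 3.68, SE 0.13; adjusted p = 5.1e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its neighbouring copies Tuba1a (−0.36) and Tuba1b (−0.05) are similar in sequence, so reads they share are uncertain. Adi1, an enzyme of the methionine salvage pathway, rose 2.92 fold, from 25.9 ± 2.22 to 74.3 ± 1.26 CPM. Kirrel2, an adhesion molecule of the nephrin family, rose 3.52 fold. Plvap, a protein of endothelial diaphragms, rose 2.21 fold, Calr3, a calreticulin paralog, 1.99 fold, and Ocel1 1.93 fold. Ocel1, Plvap and Calr3 lie within 5 Mb of each other on chromosome 8, which also holds Hsd17b2. Hsd17b2 (1.99 fold), Shisa3 (1.83 fold) and Tbx20 (1.83 fold) also passed, but each lost its call without any 1 of KO replicates 1, 2 and 3, at 0.802 to 2.08 CPM on average. Rprl3 had 7138 reads in KO and 2 in WT, a ratio of 2183 after scaling (95% interval 604 to 18032), and Rprl2 311 against 2, a ratio of 95.1 (26.1 to 789). Both are copies of the RNase P RNA gene Rpph1, which itself differed by −0.06, so the source of these reads is uncertain.

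Among the 12 lower genes named by the rule, the deepest falls were in Fggy and Rec8. Fggy, a carbohydrate kinase gene, fell from 6.22 ± 0.768 to 0.193 ± 0.183 CPM (SD, n = 3 each), by 4.99 on the log2 scale (SE 0.36). Rec8, a meiotic cohesin subunit, fell from 19.3 ± 1.71 to 1.29 ± 0.267 CPM (−3.88, SE 0.15). Kcnq1ot1, an imprinted nuclear non-coding RNA, fell from 243 ± 35.3 to 58.0 ± 2.37 CPM, by 2.06 on the log2 scale (SE 0.10). Other non-coding genes fell as well: the microRNA genes Mir384 (−2.58), Mir341 (−2.37) and Mir1188 (−2.10), the small nucleolar RNA gene DQ267102 (−2.04), and the transcripts 6430411K18Rik (−2.66), C920006O11Rik (−2.59) and Phxr4 (−2.13). Col24a1, a fibrillar collagen (−2.07), and Mpp4, a scaffold protein best known from photoreceptors (−1.99), completed the 12. Adjusted p for these 12 genes ranged from 7.85e-07 (Rec8) to 0.00466 (Phxr4) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Small RNA genes lie within longer host transcripts, so their reads can stem from the host. Reads outside genes were 34.3% of WT and 17.3% of KO libraries beside these falls.

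**Figure D3:**
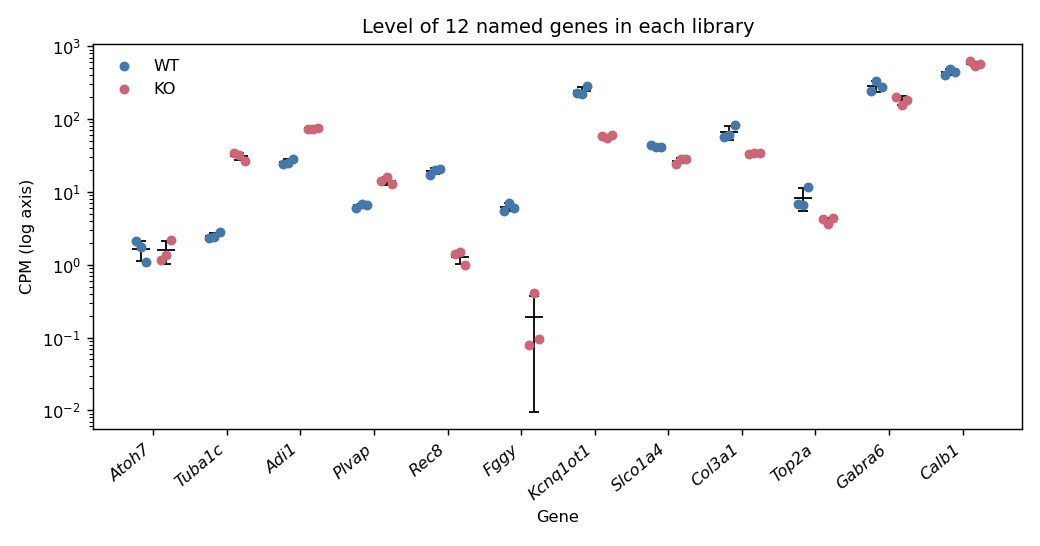
Points are the CPM of each library on a log axis (y axis) for 12 named genes (x axis), WT and KO side by side, with horizontal marks at the mean and bars of ± SD (n = 3 each; a bar that would reach 0 is clipped). Atoh7 overlaps between the groups, while Tuba1c lies at 31.0 CPM in KO against 2.51 in WT and Rec8 at 1.29 against 19.3.

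Markers of blood vessels fell in KO. Of 20 endothelial and mural cell genes, 14 fell, 0 rose and 6 did not pass, with a median log2 fold change of −0.48 and 17 lower when adjusted over the list alone. Vtn, a pericyte-enriched adhesion protein gene, fell from 57.7 ± 2.94 to 36.2 ± 0.426 CPM (−0.67, SE 0.06), Slco1a4, an endothelial transporter, from 42.3 ± 1.58 to 26.9 ± 2.12 CPM (−0.65, SE 0.08), and Cldn5, the endothelial tight junction claudin, from 25.8 ± 1.86 to 16.4 ± 0.215 CPM (−0.65, SE 0.08; SD, n = 3 each). The list passed camera (adjusted p = 1.47e-07), and fry gave an adjusted p of 0.0216. With an estimated correlation camera gave adjusted p = 0.680. The adjustment gave most lists this same value, so it does not rank them. Unadjusted, camera with an estimated correlation gave the called lists p from 0.0394 (vessels) to 0.499 (ribosomal proteins). Plvap, also of endothelium, is not on the list and rose. Without WT replicate 3 the list had 14 lower members and without WT replicate 1 it had 11; without KO replicate 3 it had 7 and without KO replicate 2 it had 9.

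Genes of meningeal fibroblasts moved the same way, with 8 of 18 lower, 0 higher and 10 not passed, a median of −0.36, and 10 lower when adjusted over the list alone. The collagen genes Col3a1 (−0.95, SE 0.13) and Col1a2 (−0.59, SE 0.12), the matrix proteoglycan gene Ogn (−0.50, SE 0.09) and the transcription factor Foxc1 (−0.37, SE 0.10) fell. Camera gave an adjusted p of 6.54e-05, and adjusted p = 0.680 with an estimated correlation; fry gave an adjusted p of 0.115. Without WT replicate 2, 5 members were lower, and without KO replicates 1, 2 and 3 the numbers were 3, 4 and 3. Choroid plexus epithelium, the tissue of the adjoining ventricle, had 0 of 18 genes past the threshold in edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 1 with sample quality weights; 0 when adjusted over the list alone), with Enpp2 at −0.21 and Kcnj13 at −0.35. Reads outside genes were 34.3% of WT and 17.3% of KO libraries beside each of these lists, WT replicate 3 held the Rn45s excess, and WT replicate 1 had the female pattern.

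**Figure D4:**
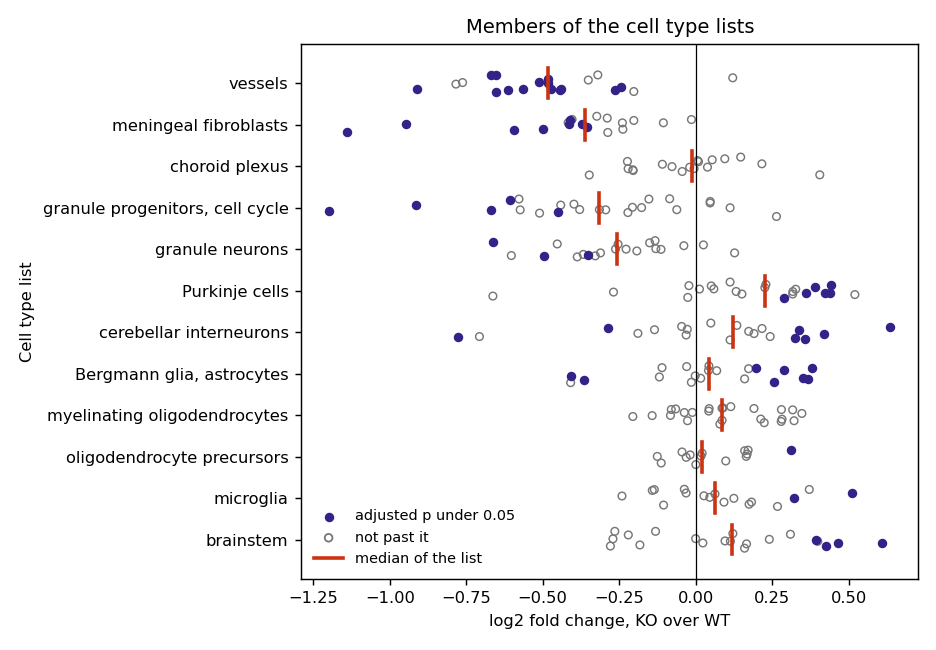
Each point is a gene of a cell type list (y axis) at its log2 fold change, KO over WT (x axis); filled points have an adjusted p under 0.05 and vertical bars mark the median of the list. The vessel list (median −0.48) and the meningeal list (median −0.36) lie to the left of 0, and the choroid plexus list (median −0.01) does not.

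Neuronal lists moved in different directions. Of 22 Purkinje cell genes, 6 rose, 0 fell and 16 did not pass (median 0.23; 9 higher and 1 lower when adjusted over the list alone). Dner, a Notch ligand of Purkinje cells, rose from 378 ± 27.3 to 507 ± 37.3 CPM (0.42, SE 0.08), and the calcium-binding protein gene Calb1 from 447 ± 41.7 to 574 ± 43.5 CPM (0.36, SE 0.08; SD, n = 3 each). Of 20 granule neuron genes, 3 fell and 17 did not pass (median −0.26; 3 lower when adjusted over the list alone): Gabra6, a GABA receptor subunit of granule cells (−0.66, SE 0.14), the carbonic anhydrase Car4 (−0.50, SE 0.12) and the phosphodiesterase Pde1c (−0.35, SE 0.11). Of 23 genes of granule cell progenitors and the cell cycle, 5 fell and 18 did not pass (median −0.31; 6 lower when adjusted over the list alone), including the cyclin Ccnb2 (−1.20, SE 0.24), the topoisomerase Top2a (−0.92, SE 0.19) and Dcx, a protein of migrating neurons (−0.45, SE 0.10). Camera gave adjusted p of 0.00416 for the Purkinje list, 0.0137 for the granule neuron list and 0.00416 for the progenitor and cell cycle list. With an estimated correlation camera gave each of these lists adjusted p = 0.680. Fry gave adjusted p of 0.331, 0.331 and 0.0389 in this order. The Purkinje list did not pass camera without WT replicate 1 (adjusted p = 0.0819), and the granule neuron list did not without WT replicate 2 (0.0874), WT replicate 3 (0.0539), KO replicate 2 (0.0575) or KO replicate 3 (0.0742). Without KO replicates 1 and 3, 1 Purkinje gene each was higher, and without WT replicate 1, 1 was lower. Of granule neuron genes, 8 were lower without WT replicate 1, 6 without KO replicate 1, 1 each without WT replicates 2 and 3 and KO replicate 2, and 0 without KO replicate 3. In turn, 2, 1 and 2 genes of the progenitor and cell cycle list were lower without WT replicate 2, KO replicate 2 and KO replicate 3. With all libraries, its members Gli1 (−0.31), Mycn (−0.22), Hhip (−0.15), Ptch1 (0.11) and Sfrp1 (0.26) did not pass. The falls on this list thus do not single out granule cell progenitors. Beside these lists, reads outside genes were 34.3% of WT and 17.3% of KO libraries.

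Voltage-gated channel genes changed in both directions, 11 higher and 4 lower of 26, with 11 not passed (median 0.18; 11 and 4 when adjusted over the list alone). The sodium channel subunit Scn4b (0.56, SE 0.11) and the calcium channel subunit Cacna2d2 (0.41, SE 0.07) rose, and the calcium channel Cacna1e fell by 0.43 (SE 0.08). Of 21 cholesterol synthesis genes, 5 rose and 16 did not pass (median 0.12; 7 higher when adjusted over the list alone), among them Acat2 (0.28, SE 0.06) and the synthases Fdps (0.31, SE 0.08) and Lss (0.29, SE 0.09). Of 16 glucocorticoid-responsive genes, 3 rose (Tsc22d3 at 0.23, Sult1a1 at 0.43 and Zbtb16 at 0.31) and 13 did not pass, with 3 higher when adjusted over the list alone. Of 52 genes of oxidative phosphorylation, 6 rose, such as Sdhb (0.34, SE 0.06), and 46 did not pass (median 0.06, mean −0.01; 4 higher when adjusted over the list alone). Of 68 ribosomal protein genes, 9 rose, 1 fell and 58 did not pass (9 and 1 when adjusted over the list alone), with Rps19 at 0.43 (SE 0.06) and the laminin receptor gene Rpsa at −0.27 (SE 0.06). Camera called all 5 lists higher, with adjusted p of 0.0182, 0.00416, 0.0379, 0.0413 and 0.0469 in this order, and for each adjusted p = 0.680 with an estimated correlation. Fry gave adjusted p of 0.163, 0.163, 0.331, 0.630 and 0.736. Without WT replicate 1 the glucocorticoid (0.170), oxidative phosphorylation (0.429) and ribosomal (0.367) lists did not pass camera, and without WT replicate 3, the library with the Rn45s excess, 19 oxidative phosphorylation and 24 ribosomal genes were higher. With the trend on GC content and length removed, a setting added after seeing the data, the glucocorticoid (0.0827, median 0.12 against 0.13) and ribosomal (0.192, median 0.05 in both) lists did not pass camera. The oxidative phosphorylation list also did not pass without WT replicate 2 (0.0997), KO replicate 1 (0.0508) or KO replicate 3 (0.0742), the ribosomal list without WT replicate 2 (0.225) or KO replicate 3 (0.164), and the glucocorticoid list without WT replicate 2 (0.0874) or KO replicate 3 (0.136). Without KO replicates 1, 2 and 3, the higher members numbered 6, 5 and 6 for channels, 3, 0 and 0 for cholesterol, 0, 0 and 0 for glucocorticoid, 1, 1 and 1 for oxidative phosphorylation and 3, 2 and 1 for ribosomal proteins; without WT replicate 2 they numbered 6, 2, 0, 3 and 3. Without WT replicate 1, 1 cholesterol and 0 glucocorticoid genes were higher, and without WT replicate 3, 5 glucocorticoid genes were. Lower channel genes numbered 2, 2, 2, 1 and 1 without WT replicates 1 and 2 and KO replicates 1, 2 and 3. Lower ribosomal genes numbered 0 without WT replicate 2, KO replicate 1 or KO replicate 2. Reads outside genes were 34.3% of WT and 17.3% of KO libraries beside these lists too.

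Camera called 10 lists between the genotypes and up to 11 between groups that mix them. It did not call the other lists, with adjusted p from 0.0784 (myelinating oligodendrocytes) to 0.889 (genes that differ between strains). As a test of a shift in 1 direction, it can miss lists whose genes change both ways. Glia changed gene by gene. Bergmann glia and astrocytes had 6 of 20 genes higher and 2 lower (6 and 2 when adjusted over the list alone). The glutamate transporter Slc1a2 was at 0.38 (SE 0.09) and Fabp7 at −0.37 (SE 0.09). Microglia had 2 of 17 higher (3 when adjusted over the list alone), the fractalkine receptor Cx3cr1 (0.51, SE 0.09) and the protease Ctss (0.32, SE 0.08). Oligodendrocyte precursors had 1 of 14 higher, Cacng4 at 0.31 (1 when adjusted over the list alone), and myelinating oligodendrocytes had 0 of 24 in edgeR (8 at an unadjusted p under 0.05, 7 by DESeq2, 4 by limma-voom and 6 with sample quality weights), with Mbp at 0.32 (SE 0.11). Interneurons of the cerebellum had 5 of 20 higher and 2 lower (6 and 3 when adjusted over the list alone): Npy, a neuropeptide, rose by 0.64 (SE 0.14), and Eomes, a marker of unipolar brush cells, fell by 0.78 (SE 0.13). Brainstem genes had 4 of 20 higher (4 when adjusted over the list alone), the glycine receptor Glra1 (0.43), the noradrenaline enzyme Dbh (0.47) and the cholinergic genes Slc5a7 (0.39) and Chat (0.61). Proneural factors had 0 of 11 past the threshold in edgeR (2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by either form of limma-voom). Leaving out WT replicates 1, 2 and 3 and then KO replicates 1, 2 and 3, in this order, gave 3, 1, 7, 0, 3 and 0 higher and 2, 1, 2, 3, 1 and 1 lower genes of Bergmann glia and astrocytes. For interneurons the order gave 5, 3, 6, 1, 2 and 1 higher and 1, 2, 2, 1, 1 and 1 lower genes, and for brainstem 4, 4, 4, 2, 2 and 1 higher. Higher members numbered 2, 1, 3, 2, 1 and 1 in microglia, 0, 0, 3, 0, 0 and 0 in oligodendrocyte precursors and 0, 0, 4, 1, 0 and 0 in myelinating oligodendrocytes. Without WT replicate 3, 1 myelinating gene was lower. Without WT replicate 1, 4 proneural factors were lower. Camera called brainstem genes without WT replicate 2 (0.0432) or KO replicate 1 (0.0155) and microglia without KO replicate 2 (0.0317). It called myelinating oligodendrocytes without WT replicate 2 (0.00783) or KO replicate 1 (0.0447).

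Glutamate receptor and scaffold genes had 4 of 28 higher and 2 lower, the lower ones being the receptor subunits Gria2 (−0.62) and Grik2 (−0.63), and axon guidance genes had 1 of 33 higher and 3 lower (median 5.83e-04, mean −0.01, camera direction up). Clock genes had 3 of 18 higher and 4 lower, heat shock genes 1 of 17 higher and 4 lower, and interferon-induced genes 1 of 21 higher and 3 lower. Genes that differ between strains had 2 of 10 higher (median −0.04, camera direction up), Cd59a at 0.46 and H2-D1 at 0.32. The log2 fold changes of this strain list had a mean of −0.18 and an SD of 0.57. Fry without regard to direction gave it an unadjusted p of 9.32e-04, and glutamate receptor and scaffold genes 4.05e-06. Immediate early genes (21 measured), blood cell genes (8) and sex-linked genes (4) had 0 past the threshold in edgeR, DESeq2 and both forms of limma-voom, with 3, 1 and 0 at an unadjusted p under 0.05 in edgeR. Retinal lists had 1 of 4 measured photoreceptor genes lower (Rcvrn, −2.42, at 0.651 ± 0.376 CPM in WT, SD, n = 3), 1 of 11 inner retina genes higher and 1 lower (Slc6a9 at 0.21 and Onecut2 at −0.33), and 2 of 20 ganglion cell genes higher (Thy1 at 0.28 and Tubb3 at 0.26), genes that brain neurons also express. When adjusted over the list alone the counts were 4 and 2 for glutamate receptors, 1 and 1 for axon guidance, 3 and 4 for the clock, 1 and 6 for heat shock, 1 and 3 for interferon, 2 higher and 1 lower for strain genes, 0 and 1 for photoreceptors, 1 and 1 for inner retina, 2 and 0 for ganglion cells, and 0 for the others. Leaving out WT replicates 1, 2 and 3 and then KO replicates 1, 2 and 3, in this order, gave 3, 1, 5, 0, 1 and 0 higher and 3, 1, 4, 1, 0 and 1 lower clock genes. Heat shock genes had 0, 0, 2, 0, 0 and 0 higher and 3, 3, 5, 1, 1 and 0 lower. Interferon-induced genes had 0, 0, 1, 0, 0 and 1 higher and 4, 1, 4, 1, 2 and 0 lower. In the same order there were 3, 2, 4, 0, 0 and 1 higher and 2, 2, 3, 2, 2 and 2 lower glutamate receptor and scaffold genes. Axon guidance genes had 3, 0, 1, 1, 0 and 0 higher and 4, 0, 4, 2, 0 and 0 lower. Strain genes had 1, 0, 2, 0, 0 and 0 higher. Photoreceptor genes had 1, 1, 1, 1, 0 and 0 lower, and 1 higher without WT replicate 3. Inner retina genes had 1, 0, 1, 0, 0 and 0 in each direction, and ganglion cell genes 3, 0, 5, 1, 0 and 0 higher. Without WT replicate 1, 3 sex-linked genes were lower. Without WT replicate 3, 1 blood cell gene was higher and camera called the ganglion cell list (0.00508).

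Markers of cerebellar cells were abundant and those of photoreceptors near 0 in all 6 libraries. With Rn45s left out of the totals, Gabra6 of granule cells was at 280 ± 81.4 CPM, Pcp2 of Purkinje cells at 224 ± 56.5 CPM and Gdf10 of Bergmann glia at 223 ± 30.6 CPM (SD, n = 6). Pou4f2 of retinal ganglion cells was at 2.28 ± 1.45 CPM (SD, n = 6). The median over the granule neuron list was 149 to 212 CPM in each library, over the photoreceptor list 0.0925 to 0.192 CPM, over the inner retina list 0.416 to 1.07 CPM, and over the list of retinal ganglion cells, whose genes brain neurons also express, 32.9 to 45.9 CPM. No test was made, since these are levels within libraries.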

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

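The tests on single libraries, on nuclear RNAs, on vessels and meninges, on chromosome windows and on the region of Atoh7 were chosen after the results were seen; the counts over other splits of the libraries were planned before. Reads with several places in the genome, which no comparison of genes uses, made up a larger share of every KO library than of any WT library, with a mean of 9.28% ± 0.507 in KO and 7.39% ± 0.443 in WT (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible).

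Genes lower in KO included RNAs that stay in the nucleus, while reads outside genes were 34.3% of WT and 17.3% of KO libraries. The library with the Rn45s excess, WT replicate 3, is argued against as the only source, since 2096 genes fell without it, 1552 of them among the 1587, and so is the female library, since 1392 fell without WT replicate 1, 1229 of them shared. More nuclear or unspliced RNA in the WT libraries stays open, and so does, untested, a batch or protocol of preparation that differs by genotype, which would bear on every difference between KO and WT. Neither can be told apart from an effect of the deletion, because the share of reads outside genes separates the libraries exactly as genotype does (two-sided exact permutation p = 0.1, the smallest possible). In genes lower without WT replicate 3, that library lay at a median of 0.02 on the log2 scale above the other WT libraries (−0.02 over all genes), although its ratio of reads outside genes to reads in genes other than Rn45s was 2.95 against 0.617 and 0.612.

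Vessel and meningeal genes were lower together. WT replicate 3 is argued against as the only source, since 20 of the 38 members fell without it, against 22 with it. A smaller share of vessels and meninges in the KO samples, from dissection or from biology, stays open: 37 of 38 members had a negative log2 fold change, but these genes make up the pattern, so their count restates it. Of abundant members, Col1a2 (114 to 75.0 CPM), Col3a1 (66.8 to 34.0 CPM), Vtn (57.7 to 36.2 CPM) and Rgs5 (57.0 to 41.5 CPM) fell. Igf2 (241 to 196 CPM) and Ptgds (433 to 401 CPM) did not pass the threshold, and the rise of Plvap (2.21 fold) goes the other way. Of the named members, Vtn, Slco1a4, Cldn5, Itm2a, Col3a1 and Ogn kept their calls under every alternative, the read assignment covariate included. Col1a2 lost its call under 2 alternatives and Foxc1 under 8. The effect of the deletion and the difference in read assignment both stay open, as they separate the same libraries. Within groups the covariate varied almost only through WT replicate 3, so calls kept with it do not exclude read assignment.

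Large changes of single genes and changed genes that sit together on chromosomes form the last pattern. The densest window of 5 Mb for genes at least 1.5-fold higher lay on chromosome 8 with 6 of 87 tested genes (Ocel1 and Plvap among them). The average expectation was 0.320, and 2 of 1000 permutations of the calls gave a window as dense (permutation p = 0.003). For all higher genes the densest window also lay on chromosome 8. It held 12 of 42 tested genes (Hsd17b2 among them) against 2.73 on average (permutation p = 0.007). Strain haplotypes that differ between the WT and KO mice could give such clusters, and so could genes regulated together; genotypes of the mice were not analysed here. An effect in cis within 5 Mb of Atoh7 was not resolved, with 16 of 67 genes changed (23.9% against 16.6% elsewhere, odds ratio 1.58, 95% interval 0.838 to 2.82, two-sided Fisher's exact test p = 0.136). An effect of the deletion away from its own region stays open, untested.

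The 6 libraries split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2585 changed genes, 998 higher, 1587 lower and 5 near Atoh7. The highest of the other splits gave 0 for each by edgeR (1 of 10 splits reached each real count). At an unadjusted p under 0.05 the other splits had 82 to 639 genes against 5045 in the real split. Every other split puts WT and KO libraries in the same group. A difference between WT and KO then widens the spread within groups and lowers these counts. They are thus no measure of the calls that chance alone gives. Other tools were not run on the splits. For lists past camera the real split gave 10 and the highest of the others 11. Of the 10 splits, 4 gave at least 10, the real split included. As many lists as between the genotypes were thus called between mixed groups. Mixed groups hold unequal numbers of WT and KO libraries and so keep part of a difference between genotypes. These list counts are therefore no measure of chance either.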

How the results depend on the processing

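The read assignment covariate, the GC and length trend and the list counts without WT replicates were added after seeing the data. All other settings were planned. Within groups the read assignment covariate varied almost only through WT replicate 3, so its results cannot separate read assignment from that library. Sample quality weights gave 4092 changed genes, 1725 higher and 9 near Atoh7; the read assignment covariate gave 1422 changed, 561 higher, 861 lower, 3 near Atoh7 and 6 lists, with 175 of the higher and 653 of the lower genes among those of the main fit. A minimum change of 1.2 fold gave 599 changed genes and an adjusted p under 0.1 gave 3960. The count of lower genes stayed within 1.5 times under all other settings except the block and some left-out replicates. Replicate numbers did not pair the libraries, as same-numbered deviations correlated at −0.18, −0.14 and −0.10; a replicate block gave 1073 changed genes, 252 higher, 821 lower and 3 near Atoh7. Leaving out each replicate in turn gave 1041 to 3719 changed genes, 245 to 1623 higher, 796 to 2096 lower, 3 to 7 near Atoh7 and 6 to 11 lists; fewer libraries were then tested. For lists, the sex covariate gave 6, the estimated correlation 0 and fry 2. The cause of these moves was not tested.

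Atoh7 ranged from −0.49 to 0.0141 without a replicate, and the sex covariate, which absorbs WT replicate 1, gave 0.0145, and the read assignment covariate −0.68; no setting passed its threshold. The granule list exceeded the photoreceptor list by 7.28 on the log2 scale with CPM and by 9.86 with raw counts. Removing the GC and length trend moved the share of higher genes among changed ones from 38.6% to 47.6%, with 1255 higher and 1381 lower; log2 fold change and GC content correlated at 0.166 across genes (Spearman), which are not independent replicates. Medians of the 10 lists past camera kept their sign under RLE and upper quartile scaling.

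Of 85 named genes with a call, 28 passed under each of the 20 alternatives that tested them and 57 lost the call under at least 1; 0 reversed. Calls lost without WT replicates 1 to 3 numbered 15, 25 and 3, and without KO replicates 1 to 3 29, 34 and 40; the read assignment covariate ended 53, the replicate block 37 and the sex covariate 15. Named genes without a call turned sign with the read assignment covariate in Ccar1 (0.0137), Olig1 (−0.0082), Kcnj13 (0.041), Tfap2a (0.0715) and Alas2 (−0.10). WT replicate 3, with 6015125 gene reads outside Rn45s, limits the precision for low genes.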

Other observations

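The 2 lists of nuclear RNAs below were written after the first results were seen, and so were their tests. Of 14 nuclear non-coding RNAs, 11 fell, 1 rose and 2 did not pass (median −1.29; 12 lower when adjusted over the list alone). Malat1, a nuclear speckle RNA, fell by 1.65 on the log2 scale (SE 0.15), Meg3, an imprinted RNA, by 1.95 (SE 0.13), Ftx of the X-inactivation centre by 1.80 (SE 0.10) and Miat by 1.36 (SE 0.12), while Peg13 rose by 0.32 (SE 0.06). Of 21 genes whose transcripts are known to keep introns in the nucleus, 18 fell and 3 did not pass (median −0.84; 20 lower when adjusted over the list alone), among them the splicing kinases Clk1 (−1.59, SE 0.09) and Clk4 (−1.32, SE 0.08) and the RNA-binding protein genes Pnisr (−1.43, SE 0.11) and Luc7l3 (−1.49, SE 0.15). Adjusted together with the 31 planned lists, both passed camera with the preset correlation (adjusted p = 4.33e-09 and 6.78e-16) and neither passed with an estimated correlation (adjusted p = 0.420 and 0.434). In the same adjustment both passed fry (adjusted p = 7.24e-04 and 0.00155). Without WT replicate 3, 11 and 19 members were lower, and with the GC and length trend removed 9 and 18. Reads outside genes were 34.3% of WT and 17.3% of KO libraries.

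Long non-coding genes as a class were lower more often, 88 of 558 (15.8%) against 1368 of 14207 protein-coding genes (9.63%; two-sided Fisher's exact test p = 8.64e-06, genes not being independent), and 8 (1.43%) against 962 (6.77%) were higher. On chromosome 12 the imprinted cluster of Meg3, Mirg and many small RNAs formed the densest 5 Mb window of lower genes. There 22 of 47 tested genes were lower against 4.75 on average (permutation p = 0.001, the smallest that 1000 permutations give). The permutation treated genes as independent, while reads of small RNA genes can stem from shared host transcripts. Its p therefore overstates the evidence for this window. A window on chromosome 17 held 10 lower genes of 22, of which 8 carry Zfp names of zinc finger proteins, and a window on chromosome X near Ftx held 9 genes at least 1.5-fold lower of 37; WT replicate 1, the only library with a female pattern, is in the WT group.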
